A study of Orbicella faveolata with 48 samples.

How the data were processed

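Tissue of the mountainous star coral Orbicella faveolata, a reef-building coral that houses photosynthetic algae in its cells, was sequenced as RNA in 48 libraries. Fragments came from inshore and offshore reefs of the Florida Keys. Each was held at a control temperature of 30 °C or, after a gradual rise, at a higher one, and was sampled at 5 or 31 days. The heated fragments of 5 days stood at 33 °C and those of 31 days at 32 °C, so temperature and duration changed together between the 2 times. The 8 groups (habitat, temperature arm and day) held 9 inshore libraries each or 3 offshore libraries each. Every library carried a colony tag, such as A4, and 1 of 7 genotype labels, 4 inshore (In1, In2, In3 and In4) and 3 offshore (O1, O2 and O5). Tags stood in both arms of a day for 12 pairs at 5 days and 11 pairs at 31 days.

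RNA was extracted from whole tissue with a column kit and made into stranded mRNA libraries, per the labels' protocols. The deposited values are estimated counts per assembled transcript, 1 table for coral features (87440) and a second table for other features (93246) that its name marks as symbiont. Both tables are named for kallisto, a tool that estimates counts by pseudoalignment, while the submitters' processing notes name Trimmomatic 0.36, a read trimmer, and RSEM, a count estimator, with no role. Which of them made the counts, and the reference used, are not given in the sources used here. Estimated counts can split reads between near-identical transcripts, so a feature stands for an assembled sequence and not for a gene. The files do not pair features with gene names, and the lists of genes fixed beforehand by product name could not be applied. No reference was used here. The authors' estimated counts were not whole in 23.6% of the coral values and 3.07% of the second table's values and were rounded for all tests. All columns but 1 were mapped to a sample by a name equal to that in its labels. The coral column headed BL6 was read as tag BLY6 of the 5-day controls, the only sample left for it.

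Coral totals ran from 4726660 to 6686880 counts per library and totals of the second table from 67428 to 1360640. A share of all counts therefore had a 95% Wilson interval of at most ±0.032 percentage points, and the share of 1 algal set within both at most ±0.736 points. These intervals cover counting error only, since the reads carried no molecular identifiers.

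Heat responses were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr on the groups, and a quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The 24 libraries of a day entered 1 model with a term for each genotype label and a heat effect within each habitat, and the difference of both effects was tested in the same model. Habitats were compared within an arm on counts summed per genotype label, 4 against 3. The algal content of a library was taken as the log2 ratio of the second table's total to the coral total, and its change, heated minus control, was averaged per genotype and tested with an exact sign-flip permutation test. PERMANOVA (vegan 2.7.1, Euclidean distance on log2 CPM with a prior count of 2, permutations within genotype, smallest possible p 1e-04) gave the share of the spread that went with temperature and with genotype. Alternatives were DESeq2 1.42.0, other size factors, no filter, tags as a block, no genotype term, summed counts and leaving out libraries or genotypes in turn. These designs and alternatives were fixed before the data were examined. The rule for naming features was the 2 with the smallest p in each direction of each comparison, by identifier. Since the identifiers carry no names, those of the inshore response at 5 days alone are printed.

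Colony tags and genotype labels both paired the arms in the coral table. The deviations of same-tag libraries from their group means correlated at 0.51 to 0.75 over the 12 pairs of 5 days and at 0.41 to 0.71 over the 11 pairs of 31 days, against medians of -0.24 and -0.16 between inshore libraries of other genotype labels. Other tags of the same genotype label correlated nearly as highly (medians 0.61 and 0.55, against 0.62 and 0.57 for the same tag). A library's best match carried its own tag in 8 of 12 and 7 of 11 pairs, so most of the pairing goes with genotype. In the algal counts, 9 of 12 and 9 of 11 pairs exceeded 0.1, so there the tags do not pair every fragment. No 2 libraries of a group agreed within sampling noise: over 156 pairs the lowest chi-square per degree of freedom was 3.72. Where nothing says that fragments with 1 genotype label came from separate colonies, p-values over fragments measure the spread between fragments.

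Chosen after the data were seen were 2 sets of algal features. Among 37431 features of the second table with a mean CPM of 5 or more in the 24 control libraries, principal component 1 of log2 CPM held 87.9% of the variance. Set 1 took the 15420 features that correlated with it at 0.9 or more on the side of In1, and set 2 the 18033 features at 0.9 or more on the other side. Steady features, also chosen then, were those whose counts per coral count had a coefficient of variation under 0.4 over the 48 libraries, above a minimum mean level. Tests of these sets, and of offshore against inshore changes by exact permutation of genotypes, were also chosen after the data were seen.

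The edgeR procedure was tested on simulated counts with 100 features changed at each size, drawn from the real means and library sizes. Changes were placed only in features above a minimum mean count, and the largest feature spreads were capped. The shares recovered therefore do not cover tested features with lower counts. In the heat test of 5 days it recovered 91% of 2-fold and 100% of 4-fold changes inshore, and 34% and 87% offshore, among 34540 features. At 31 days the shares were 64% and 92% inshore, and 15% and 65% offshore, among 35219 features. The habitat test of controls recovered 3% and 27% at 5 days (27607 features) and 0% of either size at 31 days (27795 features).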

Results

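The coral Orbicella faveolata lives with single-celled algae that it can lose when the water warms, a loss known as bleaching. RNA libraries of coral fragments from inshore and offshore reefs of the Florida Keys were compared between a control temperature and heat, to ask how corals of the 2 habitats differ in heat tolerance. At each of 2 times, 5 and 31 days, there were 9 inshore control, 9 inshore heated, 3 offshore control and 3 offshore heated libraries. Each library gave 2 counts of RNA, those assigned to coral features (4726660 to 6686880) and those assigned to the features of the second table, here called algal (67428 to 1360640). Fragments of the 5-day heat stood at 33 °C and those of the 31-day heat at 32 °C.

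Algal RNA fell under heat at both times and in every genotype. At 5 days the algal share of all counts was 17.3% ± 2.46 (SD, n = 9) in inshore control fragments and 11.3% ± 3.13 (n = 9) in heated ones. Offshore it was 17.2% ± 2.65 (n = 3) in controls and 3.52% ± 4.29 (n = 3) under heat. The log2 ratio of algal to coral counts changed by -1.90 (SD 1.65, n = 7 genotypes), and it fell in 7 of 7 genotypes (exact sign-flip permutation test, two-sided, p = 0.0156, the smallest that 7 genotypes can give). The fall was smallest in In1, where the ratio was 1.12-fold lower under heat, followed by In2 (1.85-fold), In3 (2.0-fold), O5 (2.46-fold) and In4 (2.81-fold). It was 15.0-fold lower in O2 and 23.1-fold lower in O1. In the heated fragments of O1 (C1) and O2 (C2), 75.6% and 52.0% of the algal counts lay outside the 2 sets of features described below. There, 52 features with a steady level per coral count held 30.0% and 23.9% of algal counts.

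The mean change at 5 days was -0.88 (SD 0.55, n = 4) in inshore and -3.24 (SD 1.71, n = 3) in offshore genotypes. The difference of -2.36 did not pass an exact permutation test of the habitats (p = 0.0571, smallest possible 0.0286), and with colony tags as pairs it gave -2.49 (12 tags, exact permutation p = 0.0136). That p takes the 9 inshore tags as independent, although they belong to 4 genotypes. Counting only features of the 2 sets described below, the means were -0.92 (SD 0.56, n = 4) and -4.09 (SD 2.53, n = 3), a difference of -3.17 (exact permutation p = 0.0571). In control fragments of 5 days the algal share, averaged per genotype, was 17.7% ± 1.62 (n = 4) inshore and 17.2% ± 2.65 (n = 3) offshore (exact permutation p = 0.714).

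**Figure D1:**
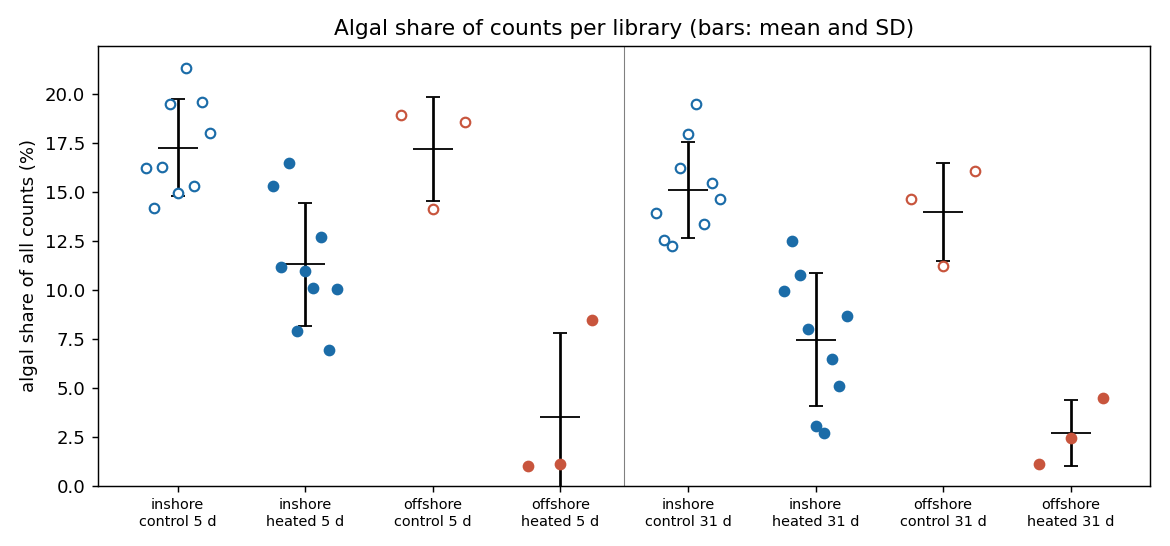
Algal share of all counts, in percent, for each of the 48 libraries (points; open control, filled heated; blue inshore, red offshore) by group, with the mean and SD as black bars. The mean of heated offshore fragments was the lowest of the 4 groups at both times, 3.52% at 5 days and 2.68% at 31 days, while their highest fragment (C5) lay above some heated inshore ones.

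At 31 days the algal share was 15.1% ± 2.45 in inshore controls and 7.46% ± 3.40 in inshore heated fragments (n = 9 each), and 14.0% ± 2.49 in offshore controls and 2.68% ± 1.69 in offshore heated ones (n = 3 each). The log2 ratio changed by -2.13 (SD 1.2, n = 7), again falling in 7 of 7 genotypes (exact sign-flip p = 0.0156). In1 fell least, 1.19-fold, and O1 most, 15.2-fold. The label O1 stood for tag C1 at 5 days and for tag C2 here, and C2 carried O2 at 5 days. Labels therefore do not follow a colony between the 2 times. The mean change was -1.66 (SD 1.21, n = 4) inshore and -2.76 (SD 1.02, n = 3) offshore, a difference of -1.11 that was within the spread of genotypes (exact permutation p = 0.257).

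Much of the algal RNA came from 2 sets of features, taken from opposite ends of the main axis of variation among control libraries, so that their alternation in controls is built in. Set 1 held 15420 features and set 2 held 18033, and 15.3% to 75.6% of the algal counts of a library lay outside both. In the 6 control libraries of In1, set 1 made up 75.1% to 99.6% of the counts of both sets. In the 6 offshore control libraries it made up 0.18% to 5.69%. Inshore controls of In3 were mixed, from 0.201% to 65.6% set 1 in single fragments. Tag B2 of 31 days held 99.4% set 1 in its control fragment, and tag B3, under the same genotype label In2, held 0.64%.

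Under heat at 5 days, offshore fragments held far less of set 2 and more of set 1 than their controls. Set 2 counts per coral count were 123-fold lower in O1, 36.7-fold lower in O2 and 13.6-fold lower in O5, against 1.53- to 2.89-fold lower in the 4 inshore genotypes. Tags of In1 and In3 went both ways. In In1, A3 was 10.9-fold lower, and A4 and A6 were 1.34- and 1.79-fold higher. In In3, D3 and D5 were 1.24- and 3.16-fold lower, and D6 was 1.10-fold higher. The log2 change of set 2 was -5.30 (SD 1.59, n = 3) offshore and -0.95 (SD 0.41, n = 4) inshore, and the difference of -4.35 had an exact permutation p of 0.0286, the smallest that 4 against 3 can give. Set 1 counts per coral count were 2.61-, 4.66- and 46.9-fold higher in heated fragments of O1, O2 and O5, and 1.12- to 4.53-fold lower in the inshore genotypes. The heated fragments of O1 and O2 held 6031 and 10592 set 1 counts, within the 1736 to 11950 of the 5-day controls rich in set 2 (BLY5, BLY6, B4, C1, C2 and C5), while that of O5 held 370786. The offshore minus inshore difference of 4.22 in log2 change of set 1 also had an exact permutation p of 0.0286. In2 and In4, like O1 and O2, held few set 1 counts in either arm, so their changes compare low counts.

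**Figure D2:**
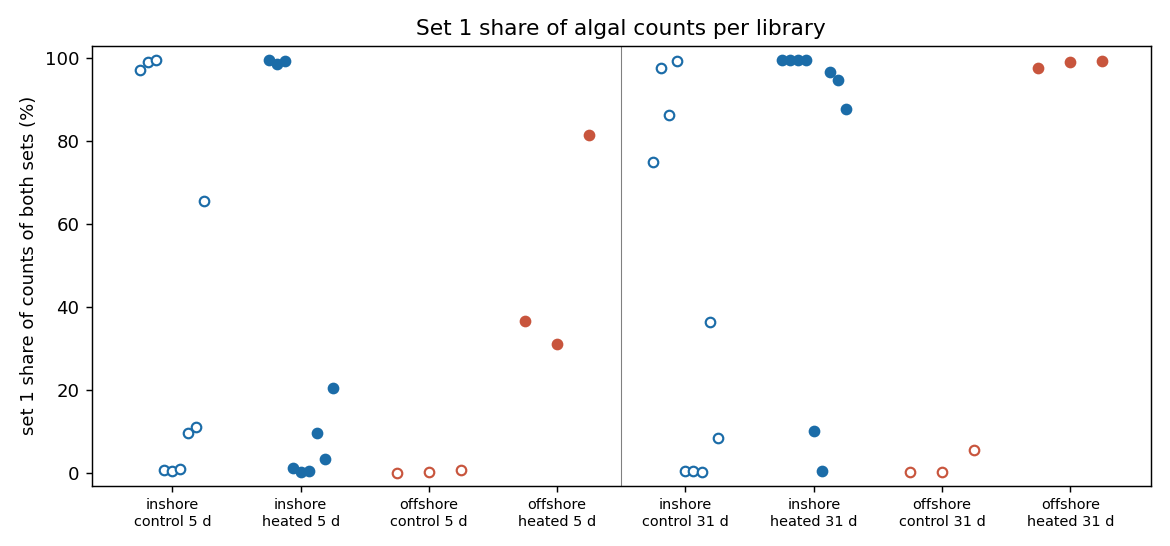
Set 1 share of the counts of both algal sets, in percent, for each of the 48 libraries (points; open control, filled heated; blue inshore, red offshore) by group. Offshore control fragments lay at or under 5.69%, and offshore heated fragments of 31 days at 97.7% or more.

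At 31 days set 1 made up 97.7% to 99.4% of the counts of both sets in the 3 offshore heated fragments, against 0.247% to 5.69% in their controls. Set 2 counts per coral count were 734- to 1058-fold lower in the offshore genotypes and 5.34- to 34.7-fold lower in the inshore ones (the lowest, In2, averages 3.41-fold in B2 and 8.36-fold in B3), a log2 difference of -5.72 with an exact permutation p of 0.0286. Set 1 counts per coral count were 3.97-fold higher in heated O5, 13.8-fold in O1 and 66.6-fold in O2. Inshore, they were 9.57-fold higher in In3, 15.5-fold lower in In4 and 1.04-fold lower in In1. Of the tags under the label In2, B2 was 2.27-fold lower and B3 2.1-fold higher. The In3 value averages tags that differed greatly, D4 being 153-fold higher and D5 1.24-fold higher. D3 and D6 had no partner in the other arm. The D4 control held 0.201% set 1 and the D5 control 36.4%. Offshore genotypes had a single fragment per arm, so such spread between fragments could not be measured there. Over all 7 genotypes the set 1 share rose by 55.2 percentage points (SD 46.7), in 6 of 7 (exact sign-flip p = 0.0312), and the rise in set 1 counts per coral count did not pass the test (mean log2 change 1.58, exact sign-flip p = 0.312).

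**Figure D3:**
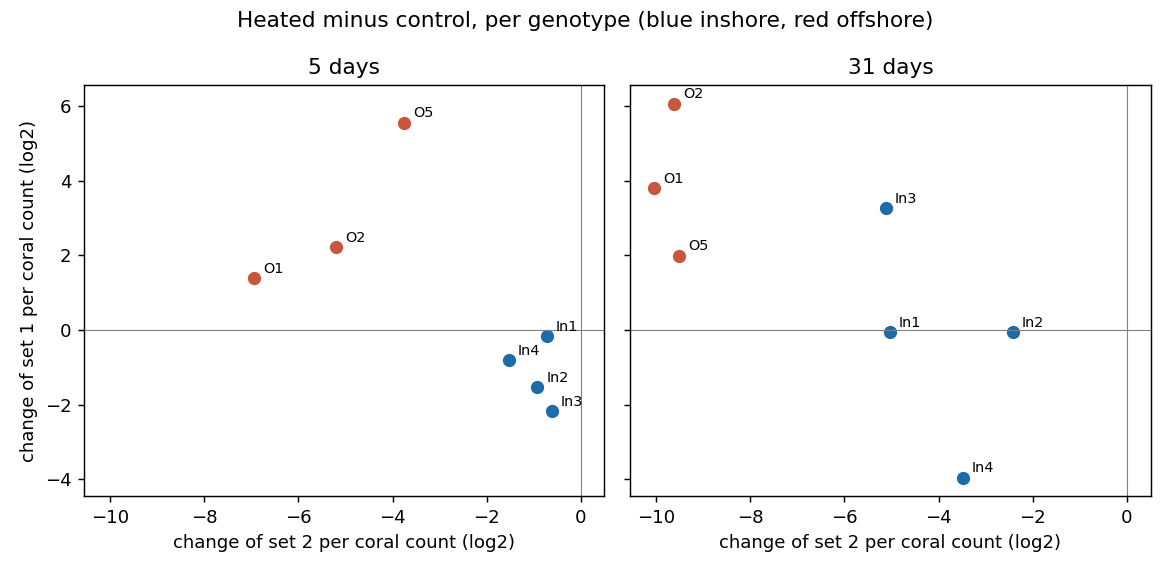
Log2 change, heated minus control, of set 2 counts per coral count (horizontal) and set 1 counts per coral count (vertical) for each of 7 genotypes at 5 days (left) and 31 days (right). Labels are not matched between the 2 times, as some stand for other colony tags at 31 days. At 31 days the 3 offshore genotypes (red) had set 2 changes between -10.05 and -9.52 with set 1 above 0, while In4, whose control held 0.66% set 1, fell in both.

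Feature by feature, tests of the second table followed these sets and depended on its scaling. At 31 days edgeR called 17586 lower and 240 higher features inshore and 17472 lower and 2412 higher offshore, of 37431. The lower features included 15562 (inshore) and 15538 (offshore) of the 15614 tested set 2 features, and 2099 of 15410 set 1 features were higher offshore. With library totals in place of TMM the inshore counts became 4 lower and 0 higher and the offshore ones 16060 lower and 15843 higher. Without In1 or In3 edgeR called 0 inshore (238 and 4930 at an unadjusted p under 0.05; DESeq2 called 17414 with all libraries). The inshore count was also 0 without an offshore control (C2, C4 or C5) or the heated C2 fragment (8309 to 10229 at an unadjusted p under 0.05). Leaving out any offshore library but the C5 control gave 0 offshore (9941 to 18088 at an unadjusted p under 0.05; DESeq2 called 24202 with all libraries). Without the C5 control the offshore balance turned around, to 12334 higher and 24 lower, and without In2 it was 17458 higher and 11801 lower. At 5 days edgeR called 0 features in either habitat, where DESeq2 called 4494 inshore and 35426 offshore. At an unadjusted p under 0.05 there were 1393 and 18902. With library totals edgeR called 8 higher and 10 lower inshore and 19456 higher and 12973 lower offshore, and with RLE size factors 8 and 165 inshore and 17545 and 20535 offshore.

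The coral itself responded broadly to 5 days of heat. Inshore, 1659 features rose and 1831 fell of 34540 tested (edgeR, adjusted p under 0.05), with a median log2 change of 0.65 among those that rose and -0.90 among those that fell. At least 2-fold changes were seen in 374 of the rising and 842 of the falling features. The count of 3490 was 825 with counts summed per genotype, 1204 without In3 and 1667 with no genotype term. The rise with the smallest p was of OFAVBQ_DN214053_c3_g2_i3, at 76.2 CPM ± 17.8 (SD, n = 9) in inshore controls and 556 CPM ± 247 (n = 9) under heat (log2 change 2.79, SE 0.18, edgeR adjusted p = 3.1e-08). OFAVBQ_DN224748_c2_g1_i5 went from 3.10 CPM ± 1.24 to 26.7 CPM ± 8.27 (log2 change 3.08, SE 0.23, edgeR adjusted p = 2.0e-07). The falls with the smallest p were of OFAVBQ_DN207917_c2_g1_i1 (log2 change -1.37, SE 0.10, edgeR adjusted p = 2.53e-07) and OFAVBQ_DN211226_c0_g1_i5 (log2 change -1.63, SE 0.13, edgeR adjusted p = 2.58e-07). All 4 moved the same way in 7 of 7 genotypes at 5 days.

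Offshore corals moved largely the same features at 5 days. In the offshore response 409 features rose and 474 fell, and 622 were called in the same direction in both habitats, where independent lists would share 44.8. No feature was called in opposite directions. Of the 3490 features called inshore, 3305 (94.7%) had the same sign offshore, and the log2 changes correlated across features at 0.48 (Pearson; Spearman 0.48), although features are not independent replicates. The 4 named features were called offshore too, with log2 changes of 2.36 (SE 0.30), 3.92 (SE 0.40), -1.43 (SE 0.18) and -0.98 (SE 0.22) in the order given (edgeR adjusted p at most 0.0188). With tags as a block the offshore count was 232 rising and 305 falling. Without 1 fragment of C1 or C2, in either arm, the offshore count fell from 883 to between 259 and 302, and OFAVBQ_DN211226_c0_g1_i5 missed the threshold offshore without either fragment of C2 or C5 (edgeR adjusted p from 0.0671 to 0.141).

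The coral responses of the habitats differed in 31 features at 5 days, 30 of which fell further offshore. Those 30 had a median log2 change of -4.71 offshore and -0.54 inshore, and 29 were called offshore. In the 31-day libraries, which took no part in finding them, their CPM followed set 2 counts per coral count: the median Spearman correlation over 24 libraries was 0.947, and 27 of the 28 tested were at 0.6 or more, against a 95th percentile of 0.382 for all tested features. Without the 105 coral-table features that tracked an algal set, edgeR called 0 differences (1746 at an unadjusted p under 0.05). These 105 were picked over all 48 libraries, those of 5 days included. Their removal therefore takes out such calls largely by construction and is no separate evidence. With those features included, DESeq2 called 47 differences, the model with tags as a block 17, and models without 1 fragment of C1 or C2 11 to 13. Of the 35 ways to choose 3 of the 7 genotypes, the real one included, 3 gave 31 or more differences.

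At 31 days fewer inshore coral features were called. In simulations the inshore test recovered 64% of 2-fold changes then, against 91% at 5 days, so the count does not measure the size of the response. 391 features rose and 445 fell of 35219, with a median log2 change of 0.92 among rising and -0.82 among falling features. With tags as a block, 77 rose and 77 fell. With counts summed per genotype edgeR called 0 (2742 at an unadjusted p under 0.05). Without genotype In3, which holds 3 fragments in each arm, edgeR called 0 (5045 at an unadjusted p under 0.05; DESeq2 called 2154 with all libraries), and without the control or the heated fragment of C4 it called 1416 and 1435. In 3 libraries of 31 days (C4 control, B2 heated and B3 heated) 106 features held 7.21% to 8.64% of coral counts, against at most 0.424% in any other library. These features were picked for at least 5 CPM in each of the 3 and at least 4 times the CPM of any other library. A gap in their share is therefore built in. Leaving these 3 libraries out gave 440 rising and 590 falling features, and 221 and 244 with tags as a block. Of the 4 named features, OFAVBQ_DN207917_c2_g1_i1 was still called lower (log2 change -1.08, SE 0.17, edgeR adjusted p = 0.00313), but not with counts summed per genotype (-1.08, edgeR adjusted p = 0.228) or without In3 (-1.01, edgeR adjusted p = 0.127). The others were not called, with log2 changes of 0.43 for OFAVBQ_DN214053_c3_g2_i3, 1.45 for OFAVBQ_DN224748_c2_g1_i5 and -0.67 for OFAVBQ_DN211226_c0_g1_i5 (edgeR adjusted p from 0.141 to 0.483). Without the 3 libraries, OFAVBQ_DN214053_c3_g2_i3 and OFAVBQ_DN224748_c2_g1_i5 passed (log2 changes 0.98 and 2.11, edgeR adjusted p = 0.00642 and 0.0103). With tags as a block besides, OFAVBQ_DN224748_c2_g1_i5 missed the threshold (log2 change 1.92, edgeR adjusted p = 0.077).

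The 2 inshore responses overlapped. Features called in the same direction at both times numbered 354 (134 rising, 220 falling), against 41.5 for independent lists, and 4 were called in opposite directions. The log2 changes correlated across features at 0.31 (Pearson; Spearman 0.31). No library entered both responses. Since temperature, duration and the recovery of simulated changes differed together, the smaller count at 31 days cannot be assigned to any of them.

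Offshore corals showed few called features at 31 days, 3 rising and 8 falling, and the difference between the habitats' responses was called for 0 features by edgeR (4808 at an unadjusted p under 0.05) and 35 by DESeq2. With tags as a block the offshore count was 4 rising and 26 falling, and DESeq2 called 303. With RLE size factors it was 0 rising and 4 falling. With B2 and B3 as separate genotypes, chosen after the data were seen, the offshore count was several times higher. The difference was then called for some features too (counts given below). Without the control or the heated fragment of C4, edgeR called 0 (1596 and 1593 at an unadjusted p under 0.05), and without In3 0 (2511), whereas without In2 92 rose and 112 fell. The log2 changes of the habitats correlated across features at -0.06 (Pearson; Spearman -0.12), and 610 of the 836 features called inshore (73.0%) had the same sign offshore. Without the 3 libraries named above, an alternative chosen after the data were seen, the correlation was 0.28 (Pearson; Spearman 0.14), and 890 of 1030 features (86.4%) had the same sign.

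A larger share of the spread in coral expression went with genotype than with heat. The 7 genotype labels enter as more terms than temperature and include habitat, so the sizes of the shares do not compare like with like. At 5 days genotype held 69.7% and temperature 6.27% of the squared distances between libraries (permutation test of temperature within genotype, p = 1e-04, the smallest possible with the permutations drawn). At 31 days the shares were 61.0% and 4.12% (permutation p = 0.0294).

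Few single features of the coral were called between the habitats within an arm. With counts summed per genotype, edgeR called 0 features in controls at 5 days (1583 at an unadjusted p under 0.05, of 27607), 0 under heat at 5 days (1688 of 29143), 1 in controls at 31 days (1909 of 27795) and 0 under heat at 31 days (1389 of 30124). DESeq2 called 160, 218, 91 and 220. In simulations of the control tests edgeR recovered 27% of 4-fold changes at 5 days and 0% at 31 days, so counts near 0 there do not decide whether the habitats differed. The tests under heat were not simulated. In the algal table the same test called 2 features in controls at 5 days (775 at an unadjusted p under 0.05) and 0 at 31 days (2579), where DESeq2 called 2 and 3975. With library totals the 5-day test called 65 features higher inshore and 2 higher offshore.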

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

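The tests of the algal sets, of the habitat difference in algal change and of the explanations weighed for both were chosen after those results were seen. So were the unrestricted splits of the inshore 5-day libraries, the offshore splits that part every tag, the calls without single offshore libraries and the slope on set 2. The tests of the correlation of 30 coral-table features with set 2 and the remaining splits were written down before their results.

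Algal counts per coral count fell further offshore than inshore at 5 days, by a log2 difference of -2.36 that missed the exact permutation test. A larger coral total offshore was argued against, since the coral total changed by only 0.116 more offshore on the log2 scale. A role of the algal set held stays open, because In1 is the one inshore genotype whose 5-day controls held set 1 alone. Without In1 the difference was -2.12, and 3 genotypes against 3 cannot give a p under 0.05. As O5 fell less than In4 (2.46- against 2.81-fold), the set held cannot be told apart from an effect of habitat for total algal counts. For set 2 counts it was argued against: without In1 the difference was -4.28, with falls of -0.61 to -1.53 in In2, In3 and In4 and of -3.76 to -6.94 in the offshore genotypes. Habitat itself, which the design names, stays open and untested apart from it.

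Set 1 and set 2 moved apart between habitats, which exact permutation tests of the 7 genotypes marked. At 5 days the set 1 share changed by 53.7 percentage points more offshore, set 1 counts per coral count by 4.22 and set 2 counts per coral count by -4.35 (log2), and at 31 days set 2 by -5.72. Part of the -5.72 goes with the low set 2 level in controls of In1 and B2. The habitat differences of 31 days in set 1 share and in set 1 counts per coral count did not pass. The set 1 rise of 5 days left the range of controls rich in set 2 only in O5. In O1 and O2 set 1 stayed within that range, though 2.61- and 4.66-fold above their own controls. Their change in share therefore combines the loss of set 2 with a set 1 change that stays within the range of controls. At 31 days set 1 counts per coral count were higher by at least 1.99 (log2) in each heated offshore genotype. This cannot decide against loss of set 2 alone, since each arm held a different, single fragment that may have differed before heat. Control fragments of In3 at 31 days ran from -11.97 (D4) to -4.22 (D5) in log2 set 1 counts per coral count. Loss of set 2 alone therefore stays open. Even carry-over of set 1 reads was argued against, with the lowest offshore heated count (35133) 65.9-fold above the lowest of the day (533). Fragments cut at random from patchy colonies would give signs at random, and the set 1 share rose in 6 of 7 genotypes (exact sign-flip p = 0.0312). That p was 0.0625 when any genotype but In4 was left out. Given the small fall of In4, this value is set by the number of genotypes and says nothing about patchiness. Single control fragments of In3 ran from 0.201% to 65.6% set 1, so a patchy mixture in single colonies could still contribute. Growth of set 1 in heated tissue remains a hypothesis.

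The test of the difference between habitats in coral response marked 31 features at 5 days, 30 of which fell further offshore. Reads from the algae counted in the coral table could account for these 30: their median Spearman correlation with set 2 counts per coral count was 0.947 in the 31-day libraries, against a 95th percentile of 0.382. The weight of single libraries stays open, since leaving out 1 fragment of C1 or C2 gave 11 to 13 calls, against 31. A test written beforehand, the median fall in each offshore tag, was dropped because the features had been found in those tags. The log-log slope on set 2 was 0.51 over 24 libraries and 0.75 over the 16 with the most set 2, under the 1 of strictly proportional reads. These features were low (median 15.9 CPM in offshore controls), and a constant was added to CPM before taking logs. That constant flattens the slope where set 2 is low, so a slope under 1 does not separate algal reads from a coral response. A coral response to the algae held stays open and was not tested. Of the 35 choices of 3 genotypes, 3 gave as many calls (31 for the real one, highest other 122), so chance was not excluded. The choice with 122 shows that a grouping other than habitat can give more calls, and what sets it apart was not tested.

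The share of coral counts taken by the 10 most abundant features was 6.80% in the BLY5 control of 31 days. The other inshore controls of 31 days held at most 5.60%, and BLY5 lay far from them by Dixon's criterion. It was the 1 outlying value of 32 groups of values tested, where chance marks about 1 group in 20. Offshore groups of 3 libraries were too small to test, and 2 high values in 1 group can hide each other. Higher shares at 31 days, in the C4 control (7.89%) and the heated B2 (9.19%) and B3 (8.19%), were therefore not marked.

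Other splits of the same libraries bear on the coral counts. For the inshore response of 5 days, 1 of 30 drawn splits, the real one, gave as many calls (3490, highest other 3), a share under 0.05. Among splits that part every tag it was again 1 of 30, and the highest other, 808, came from a split with 1 tag swapped. At 31 days it was 1 of 30 (836, highest other 38) and, parting every tag, 1 of 30 (highest other 109, with 1 tag swapped). The 6 offshore libraries make 10 splits, too few for a share under 0.05: at 5 days the real one gave 883 and the highest other 71, and at 31 days the real one gave 11 and the highest other 4245. At 31 days 3 of the 10 gave as many as the real one. The 71 and the 4245 each came from 2 splits that do not part every tag. With the genotype term such a split rests on a single parted tag, and its counterpart repeats the same fit. The splits that part every tag number 4, also too few: the real one gave 883 at 5 days (highest other 0) and 11 at 31 days (highest other 1).

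Where the real count was 0, every split gives as many, so the splits decide nothing about chance. This holds for the 35 choices of genotypes in the difference in response at 31 days (highest other 21), in the habitat tests of coral controls and heated corals at 5 days (highest others 10 and 6) and in that of heated corals at 31 days (highest other 2). In coral controls of 31 days 5 of 35 gave as many as the real 1 (highest other 2), and chance was not excluded.

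In the algal table at 5 days the real count was 0 too, which leaves the 30 inshore splits (highest other 10), the 30 that part every tag (highest other 22) and the 10 offshore ones (highest other 0; 4 of them part every tag) without information. At 31 days 1 of 30 inshore splits, the real one, gave as many as the real 17826 (highest other 2564), a share under 0.05. Parting every tag it was again 1 of 30 (highest other 41). Nearly all of these calls were lost with library totals, and all without In1 or In3. The splits shuffle fragments under the same scaling, so they say nothing about that dependence. Offshore the 10 splits were too few (real 19884, highest other 1), as were the 4 that part every tag (highest other 0). The habitat test of controls gave as many as the real 2 in 5 of 35 at 5 days (highest other 159), and chance was not excluded. At 31 days its real count was 0 (highest other of 35 choices 1), which again decides nothing.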

How the results depend on the processing

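Library totals, the removal of tracking features, the 3 libraries of 31 days (C4 control, B2 heated and B3 heated) left out, tags B2 and B3 as separate genotypes, the block for the overlap and all settings of the algal sets and of habitat differences in algal change were chosen after seeing the data. No mean change or named feature that passed its test took the opposite sign. The balance of the second table's offshore response at 31 days turned, from 2412 higher and 17472 lower features to 12334 higher and 24 lower without the C5 control and 17458 higher and 11801 lower without In2. Near-even balances of coral responses changed sides under some settings, such as 391 rising and 445 falling inshore at 31 days against 449 and 406 with RLE size factors. The mean set 1 change per coral count at 5 days, which passed no test, was 0.64 over genotypes, -0.15 with tags as pairs and -0.18 without O5. The fall of algal counts per coral count, its size at 31 days between habitats, the loss of set 2 over all genotypes and the share of coral expression that went with temperature (1.80% to 9.57% at 5 days, 3.40% to 4.83% at 31 days) kept their side of the threshold under every setting. Of 200 values of the named features under alternatives, 185 kept it, 7 lost the call and 8 gained it. Sums per gene could not be compared with transcripts, as no source used here pairs them. Offshore algal totals down to 67428 counts and a simulated recovery of at most 27% in habitat tests of controls limit what could be seen. The cause of the shifts below was not tested, apart from fewer samples or features by construction.

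Coral calls of the inshore response at 5 days (3490) were 1667 with no genotype term, 825 with counts summed per genotype, and 1204 to 3061 without 1 genotype. The offshore response (883) had 1622 with DESeq2, 537 with tags as a block, 46 with no genotype term and 259 to 636 without 1 library. The difference in response (31) had 47 with DESeq2, 61 with no filter, 17 with the block, 5 summed per genotype, and 11 to 32 with a library or genotype left out. With no genotype term edgeR called 0 (697 at an unadjusted p under 0.05), and without tracking features 0 (1746).

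The inshore response of 31 days (836) had 2154 with DESeq2, 154 with tags as a block, 465 with the block and without the 3 libraries, and 317 with no genotype term. It had 0 summed per genotype (2742 at an unadjusted p under 0.05) and 0 (5045) to 410 without 1 inshore genotype, and 770 to 1435 without 1 offshore library. The offshore response (11) had 303 with DESeq2, 4 with RLE size factors, 52 with no filter, 30 with the block, 3 with no genotype term and 1 summed per genotype. It had 22 without the 3 libraries, 49 so with the block, 96 with B2 and B3 apart, 4 without tracking features, 0 (1593) to 9 without 1 offshore library and 0 (2511) to 204 without 1 inshore genotype. The difference in response, 0 with edgeR (4808), had 35 with DESeq2, 14 with no filter, 9 with B2 and B3 apart, and 0 to 26 with a library or genotype left out.

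Habitat tests of coral controls at 5 days, 0 with edgeR (1583 at an unadjusted p under 0.05), had 14 with fragments as samples, 160 with DESeq2, 3 with no filter and 0 to 3 without 1 genotype. Under heat at 5 days, 0 (1688) became 61 with fragments as samples, 218 with DESeq2 and 0 to 1 without 1 genotype. In controls of 31 days the 1 call became 98 with fragments as samples, 91 with DESeq2, 3 without the 3 libraries, 0 with 1 fragment per genotype (1961) and 0 (1068) to 3 without 1 genotype. Under heat at 31 days, 0 (1389) became 220 with DESeq2, 2 with no filter and 0 to 1 without 1 genotype.

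In the second table the inshore response of 5 days, 0 with edgeR (1393 at an unadjusted p under 0.05), had 4494 with DESeq2, 173 with RLE size factors, 4 with tags as a block, 18 with library totals, 3 to 1327 without 1 genotype and 0 (1217) to 36 without 1 offshore library. The offshore response, 0 (18902), had 35426 with DESeq2, 38080 with RLE size factors, 2 with the block, 32429 with library totals, 0 (3993) to 34943 without 1 offshore library and 0 (18834) to 32550 without 1 inshore genotype. Of 31 days, the inshore response (17826) had 33392 with no filter, 4275 with no genotype term, 4 with library totals and 0 (238) to 14881 without 1 genotype, and 0 (8309) to 7576 without 1 offshore library. The offshore response (19884) had 31903 with library totals (15843 higher, 16060 lower), 0 (9941) to 12358 without 1 offshore library and 0 (2865) to 29259 without 1 inshore genotype. The habitat test of controls at 5 days (2) had 13917 with fragments as samples, 67 with library totals, 0 with no filter (34968) and 0 (432) to 2 without 1 genotype. At 31 days, 0 (2579) became 1 with fragments as samples, 3975 with DESeq2, 20785 with no filter and 0 without any 1 genotype (968 to 17192).

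Taking tags as pairs treats fragments of 1 genotype as independent, so the smaller p it gives between habitats does not stand for more genotypes. The habitat difference in algal change at 5 days passed with tags as pairs (-2.49, exact permutation p = 0.0136, against -2.36, p = 0.0571). That of the set 1 share at 31 days (72.7 percentage points, exact permutation p = 0.0571) passed with tags as pairs (72.3, p = 0.0121) and with B2 and B3 apart (76.5, p = 0.0179). With 6 genotypes no exact permutation of habitats can give a p under 0.05 (smallest 0.0667 for 4 against 2, higher for 3 against 3). At 5 days the set 1 share difference was then 37.9 to 62.9 points, that of set 1 counts 2.97 to 5.06 and that of set 2 counts -5.12 to -3.53 (log2), and at 31 days that of set 2 counts was -6.09 to -5.18. The rise of the set 1 share over all genotypes at 31 days was 47.9 to 64.4 points (exact sign-flip p of 0.0312 without In4 and 0.0625 without any other). The correlation of the habitats' coral changes at 31 days turned from -0.06 to 0.28 (Pearson) without the 3 libraries. The overlap of the inshore responses (354) was 82 at an adjusted p under 0.01 and 83 with the block. Without the 3 libraries, the block ended the call of OFAVBQ_DN224748_c2_g1_i5 inshore at 31 days (log2 change 1.92, edgeR adjusted p = 0.077, against 2.11 and 0.0103). Tags as a block also moved several coral and second-table counts by over 1.5 times, as given above. Beyond the changes given, the block changed no other call printed here and moved no other count that far.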

Other observations

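The tests within each algal set, their splits, the coral on and off features and the comparison of libraries that stand apart were chosen after the data were seen.

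Features of each algal set changed among themselves in the inshore fragments that kept the set. In tags with at least 100000 counts of a set in both arms, edgeR called 1549 higher and 1302 lower of 14284 set 2 features at 5 days (6 tags, 3 genotypes). It called 204 higher and 243 lower of 15416 set 1 features at 5 days (4 tags, 2 genotypes) and 75 higher and 80 lower of 15001 at 31 days (5 tags, 3 genotypes). The minimum leaves out every offshore fragment and the inshore fragments that lost a set, so the counts describe algae in tissue that kept them. Of the splits of the same libraries, 1 of 40 gave as many calls for set 2 (2851, highest other 4; parting every tag, 1 of 32, highest other 0). For set 2 both shares are under 0.05. For set 1 it was 1 of 32 at 5 days (447, highest other 51) and 1 of 40 at 31 days (155, highest other 80). The splits that part every tag, as the real one does, number 8 and 16 for set 1, too few for a share under 0.05 (highest others 4 and 27).

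A total of 102 coral features were on or off in whole libraries. With the A tags, the D tags and the BLY tags each taken as 1 colony and every other tag as its own, libraries of 1 colony differed in at most 3 of them and libraries of different colonies in at least 21. Tag BLY5 carried the label In2 at 5 days and In4 at 31 days, and its libraries differed in 0 of the 102 features. Tag C2 carried O2 at 5 days and O1 at 31 days, again with 0 differences. Tags B2 and B3, both In2 at 31 days, differed in 34 to 35. Genotype labels were therefore compared within a day and never matched between days.

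In the 3 coral libraries of 31 days named above (C4 control, B2 heated and B3 heated), TMM factors were 0.655 to 0.765, and the next lowest of all coral libraries was 0.92. Their 106 features had a median CPM of 198 there and 3.61 elsewhere. They had been picked for being at least 4-fold higher in each of these libraries than in any other.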
